A study of Mus musculus with 2 samples.

How the data were processed

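Donor T cells from the colons of 5 pooled mice were profiled on day 21 after transplantation, as 1 RNA library and 1 TCR library of the same cDNA, so that the pool is 1 sample. Recipients had received 5e+06 bone marrow cells and splenocytes holding 800000 alpha beta T cells, per the labels. The labels describe a sort on H2-Kb and TCR beta.

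The RNA values are deposited UMI counts per gene and cell barcode, as whole numbers and not normalized. Per the submitters' processing notes, Cell Ranger was used with the mm10 genome; the version is not given in the sources used here. The contig table gives the deposited read and UMI counts of each assembled TCR contig, with the authors' annotation of chain, segments, CDR3 and whether the contig is productive. Contigs marked productive made up 52.3% of 18289. A TCR reference is not given in the sources used here.

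Barcodes were kept with at least 500 detected genes and at most 10% of UMIs from mitochondrial genes. This left out 1 and 15 barcodes and kept 5333 of 5348, with a median of 4800 UMIs and 1804 genes. Scrublet, run at an expected doublet rate of 0.05, called 0 doublets, so the caller did not work and doublets remain; 232 kept cells (4.35%) had 2 or more productive TRB chains. Counts were scaled to 10000 UMIs, log-transformed and clustered from 2000 highly variable genes without TCR and immunoglobulin segments, with 30 principal components, 15 neighbours and Leiden resolution 0.8. The tools were Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

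Clusters were named "-like" only from marker lists fixed before the data were examined, where at least 3 markers were 2-fold above the other cells with at least 10 UMIs and the leading genes did not go against the name. Where more than 1 list reached this, the list with clearly most markers gave the name or the cluster was left by number, a choice made after the markers were seen. The names were rebuilt here and may differ from those of the study.

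Classes of Csf2-positive and Foxp3-positive cells were set on cells thinned to 2000 UMIs, so that detection did not follow depth; no kept cell was shallower. Levels are sums of all UMIs of a class per 10000 UMIs. Ratios carry exact conditional binomial intervals, levels exact Poisson intervals and shares Clopper-Pearson intervals, all at 95%. Genes with 0 UMIs in a class were set to a floor of 3 UMIs over the class and given as bounds, in list medians too. Such bounds take UMIs as independent and may fail where each positive cell holds several. A share of 0 is given with the share that 3 cells would make, and its Clopper-Pearson bound is higher. Cells are not replicates, so no test was made. All intervals and floors cover counting error only.

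Named genes were chosen by a rule fixed before the data were examined. In each of the 3 comparisons, they are the 12 genes with the highest and the 12 with the lowest ratio by the interval bound nearest 1, among genes with at least 50 UMIs over both classes. TCR segment, immunoglobulin, mitochondrial and ribosomal protein genes, predicted models and the genes that set the classes were left out. Up to 4 members of each of 35 gene lists with the largest bounds were added. Each list with 3 or more measured genes was described by its median log2 ratio and the percentile of this median among 10000 random lists of matched mean level. The results of some genes are not reported here. Gene positions are 1-based, from the GENCODE annotation of the mm10 assembly.

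A clonotype was the set of productive TRA and TRB CDR3 nucleotide sequences with their V and J segments, in cells with 1 productive TRB and at least 1 productive TRA chain, and it was called expanded with 2 or more cells. Sharing between clusters is the number of same-clonotype pairs across 2 clusters over the number that independence of clonotype and cluster gives.

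The ratio step was tested on simulated counts with known changes, drawn as a Poisson count per gene and class. No spread between cells was simulated. The test thus checks the computation and not how often the intervals hold in these data. For the Csf2 comparison 96.1% of 8884 intervals held the true ratio, and the interval lay on the right side of 1 for 91.2% of 34 genes changed 2-fold, 100% of 33 changed 4-fold, and 53.3% of 30 changed to 0.5. For the CD4 and CD8 comparison 95.2% of 10107 held it, and 97.0% of 33 genes changed to 0.5 were recovered. For the Foxp3 comparison 97.7% of 8920 held it, and only 32.4% of 34 genes changed 2-fold were recovered.

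Alternatives to the cell filters, doublet handling, clustering resolution, thinning, class definitions, weighting of cells and clonotype definition were listed before the data were examined, and others were added after. Gene segments in the RNA were compared with contig calls in the closing section.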

Results

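Donor T cells were profiled from the colon of mice with graft-versus-host disease, in which T cells of a graft attack the tissues of its recipient. Irradiated Balb/c mice had received bone marrow and spleen cells of C57BL/6 donors, and their colons were taken on day 21. Cells of 5 mice were pooled before donor T cells, which carry the donor class I molecule H2-Kb and TCR beta, were sorted. The pool gave 1 droplet RNA library (10x Genomics, 5' chemistry) and 1 T cell receptor (TCR) library from the same cDNA. The RNA matrix held 32772424 unique molecular identifier (UMI) counts in 5348 barcodes, with 2549 to 39138 UMIs per barcode and a median of 4795. Of these barcodes, 5333 were kept. The TCR table held 18289 contigs of 5990 barcodes, and 5133 kept cells were among them. The pool is 1 sample and no comparison has a replicate check, so no p-value was computed and every interval below is a 95% interval covering counting error only.

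The sorted cells fell into 17 clusters, most of them of CD4 or CD8 T cells, although the titles name CD4 T cells alone. The largest cluster, cluster 1, held 948 cells or 17.8% of the kept cells (Clopper-Pearson interval 16.8 to 18.8). Clusters 1, 3 and 13 were CD8 cytotoxic-like by their markers, and the heat shock genes Hspa1a and Hspa1b were among the leading genes of cluster 13. Cluster 2, with 811 cells, was Th17-like and carried Il17re, Il22, Il1r1 and Il23r. Cluster 10, with 205 cells, was Th2-like and carried Il4, Il13, Il1rl1 and Gata3. Clusters 4 and 9 were cycling-like, of CD8 and CD4 cells respectively, and clusters 11 and 12 were led by DNA replication genes such as Ung and Mcm2. Cluster 15, with 36 cells, was regulatory T cell (Treg)-like and cluster 16, with 34 cells, was interferon response-like. Clusters 14 and 15 reached 3 or more markers of further lists and were named by the list with most markers, 7 and 8. Clusters 5, 6 and 17 reached 3 or more markers of 2 lists, at close counts, cluster 11 of the CD8 cytotoxic list beside its replication genes, and clusters 7, 8 and 12 of none, so these are given by number. Cluster 5 was led by Il10, Slamf6, S1pr1 and Cxcr5, cluster 6 by Krt17, Dusp14 and Ebi3, cluster 7 by Rasl11a, Ifitm1 and Atf3, cluster 8 by Penk, Xcl1 and Ccl1, and cluster 17 by Ramp1, Nrgn and Il1r1. Cluster 14, with 69 cells, was macrophage-like by 7 markers and was led by myeloid genes such as Il1b, H2-Aa and Lyz2. Markers of fibroblasts (5, such as Dcn), epithelial cells (3, such as Krt8) and neutrophils (3, such as S100a8) were also 2-fold higher in it, with 2 or more genes of these lists in 1, 1 and 5 of its cells. Of its cells, 66.7% also had a TRB contig or a Trbc UMI (54.3 to 77.6).

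**Figure D1:**
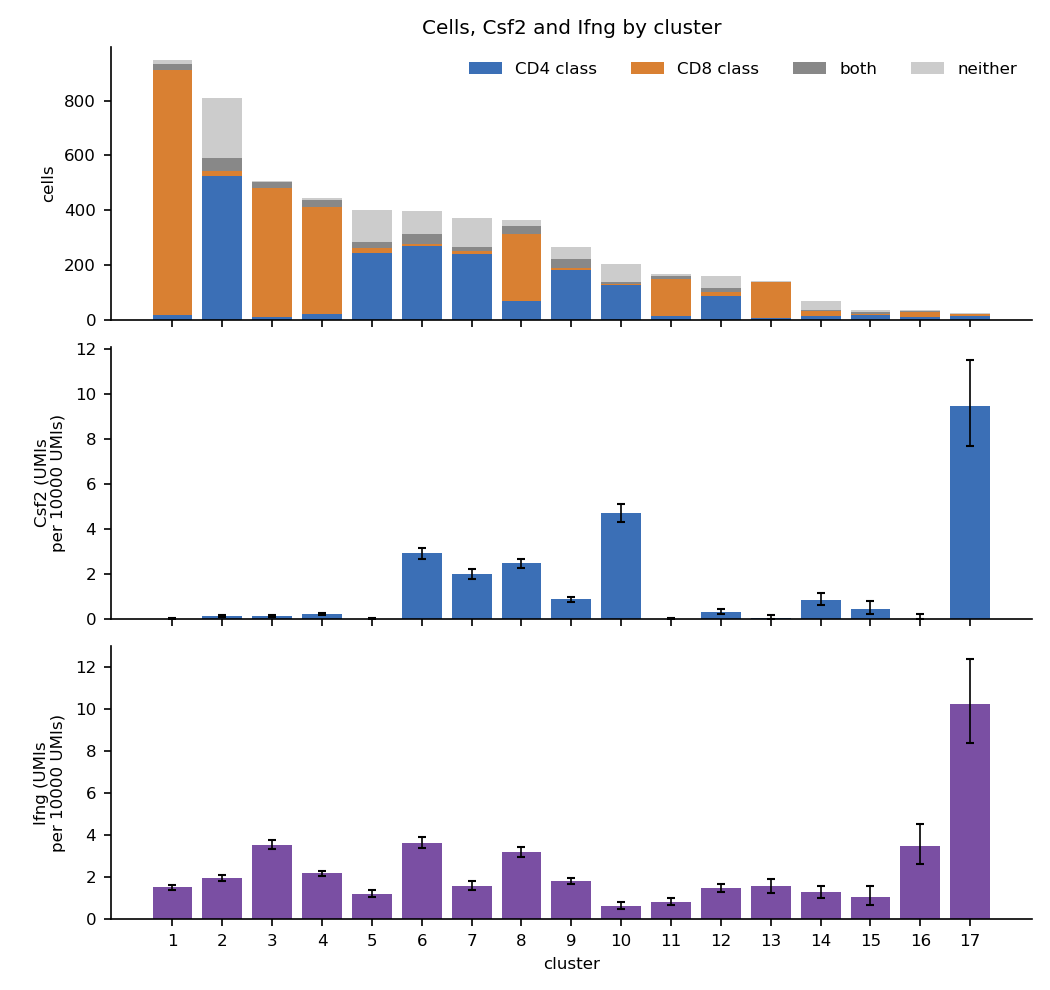
Cells per cluster, coloured by CD4 and CD8 class (top), and the summed level of Csf2 (middle) and Ifng (bottom) in UMIs per 10000 UMIs, with 95% Poisson intervals that cover counting error only. Csf2 stood at 9.47 in cluster 17 and 4.71 in cluster 10, and at 0.139 in cluster 2.

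By their Cd4 and Cd8 UMIs, more of the sorted cells fell into the CD8 class than into the CD4 class. The CD8 class, cells with a Cd8a or Cd8b1 UMI and no Cd4 UMI, held 2391 cells or 44.8% (43.5 to 46.2). The CD4 class, cells with a Cd4 UMI and neither Cd8 gene, held 1861 cells or 34.9% (33.6 to 36.2). A further 301 cells had UMIs of both lineages and 780 of neither, and these were left out of class comparisons. The 780 cells without either had a median of 3955 UMIs, against 4768 in the CD4 class and 4910 in the CD8 class. Of these 780 cells, 688 lay in clusters in which CD4 class cells outnumbered CD8 class cells, so by cluster the lineages were about equal, at 2664 cells in these clusters and 2600 in the others without cluster 14.

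Il4, Il17a, Il22 and Cd40lg were higher in the CD4 class and Prf1 and Gzmb in the CD8 class, while Ifng lay near equality, at 0.922 times the CD8 level (0.873 to 0.974). Cd40lg, the ligand by which helper cells activate antigen-presenting cells, was 29.99-fold higher in the CD4 class (24.2 to 37.5). Il17a was 66.9-fold (32.1 to 168), Il4 98.0-fold (33.1 to 479) and Il22 441-fold higher (78.6 to 17479), with 7, 3 and 1 UMIs in the CD8 class. Prf1, which encodes perforin, stood at 0.0835 times its CD8 level (0.0701 to 0.0988) and Gzmb at 0.189 (0.184 to 0.194). Ly6c2, a surface marker of memory CD8 cells, was at 0.0470 times the CD8 level (0.0414 to 0.0532). Csf2 itself was 9.94-fold higher in the CD4 class (8.64 to 11.5). With 1 cell per clonotype, the log2 ratios were closer to 0, at 2.42 for Csf2, 3.99 for Cd40lg and -3.35 for Ly6c2, and at 4.45 and 4.56 for Il4 and Il22, from the floor.

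Other genes with the largest differences included Cxcl3, a neutrophil-attracting chemokine, which was 99.5-fold higher in the CD4 class (38.5 to 368), and Il17re, part of an IL-17 family receptor, which was 45.1-fold higher (23.5 to 99.6). Wisp1, Lgals7, Ebi3 and Scin were 29.4-fold, 29.6-fold, 29.8-fold and 72.9-fold higher, and Scin had 2 UMIs in the CD8 class (interval 19.7 to 609). Krt17 and Prr29 had no UMI in the CD8 class and were at least 43.6-fold and 27.9-fold higher in the CD4 class, from a floor of 3 UMIs over the class. On the other side, Syce1 had no UMI in the CD4 class and was at least 53.9-fold lower. Gzmd was at least 43.2-fold lower, from 3 CD8 cells. Gzme stood at 0.0428 (0.0115 to 0.112), and of its UMIs 56.3% lay in 1 CD8 cell. Gzmf stood at 0.0167 times the CD8 level (0.00668 to 0.0346), Itgax at 0.0540 (0.0292 to 0.0918) and Bend4 at 0.0509 (0.0184 to 0.113). Smyd1, Susd1, Adamts14 and BC035044 had 1, 1, 1 and 2 UMIs in the CD4 class, at ratios of 0.0130 (0.000325 to 0.0739), 0.0138 (0.000345 to 0.0785), 0.0147 (0.000367 to 0.0838) and 0.02499 (0.00299 to 0.0925). With 1 cell per clonotype, the log2 ratios were 5.12 for Cxcl3, 4.23 for Wisp1, 6.20 for Lgals7 and -4.40 for Gzmf. Without its top cell Gzmd stood at -4.32.

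Among gene lists fixed before the data were examined, the Th17 list had a median log2 ratio of CD4 over CD8 class of 3.71 over 9 measured genes and the Th2 list of 3.43 over 7. Both lay above all 10000 random lists of matched level, at percentile 100. The cytokine list stood at 1.63 over 28 genes, the Treg list at 1.12 over 8 and the GM-CSF helper list at 2.03 over 6, each at percentile 100. Within it Il1r1 was 17.1-fold higher (10.5 to 29.97), while Xcl1 was lower, at 0.597 (0.552 to 0.646). The cytotoxic list stood at -1.55 over 10 genes and the CD8 cytotoxic list at -2.05 over 6, both at percentile 0. The Th1 list lay near equality, at 0.10 over 8 genes, with Il18r1 at 1.72 (1.61 to 1.84) and Ccl5 at 0.215 (0.213 to 0.218). The GM-CSF programme, NF-kappaB target, cytokine receptor, transcription factor, Tfh and naive or central memory lists stood at 0.66, 0.50, 0.48, 0.35, 0.68 and 0.41, at percentiles 100, 100, 100, 100, 99.95 and 99.56, and the cycling and interferon response lists at -0.23 and -0.21, the latter at percentile 5.65. Genes linked to tissue dissociation stress were also higher in the CD4 class, at a median of 0.40 over 14 genes. With 1 cell per clonotype, which weights clones alike and leaves out cells without a clonotype, the cytotoxic median was -1.02.

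The main question of the series is about CD4 T cells that make GM-CSF, the growth factor encoded by Csf2 (ENSMUSG00000018916; chromosome 11, 54247271 to 54249667, minus strand, mm10). Csf2 UMIs were found in 10.4% of the CD4 class (9.07 to 11.9), or 194 of 1861 cells thinned to 2000 UMIs, and in 14.7% without thinning. The share was 1.21% in the CD8 class (0.814 to 1.74), at median depths of 4768 and 4910 UMIs. In the macrophage-like cluster 14 it was 3 of 69 cells, at a median of 7360 UMIs, and in CD4 class cells of cluster 5 it was 0 of 243. Of 2724 Csf2 UMIs, 60.6% lay in the CD4 class and 8.22% in the CD8 class. The 50 highest cells held 46.8% of these UMIs, and the highest cell held 71.

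Csf2 was unevenly spread over the clusters. Of the clusters named here, cluster 8 was mostly of the CD8 class, with 69 CD4 and 243 CD8 class cells. The 194 Csf2-positive cells lay mainly in cluster 7 (24.7%, 18.8 to 31.4), cluster 6 (24.2%, 18.4 to 30.9), the Th2-like cluster 10 (19.6%, 14.3 to 25.9) and cluster 8 (13.4%, 8.95 to 19.0). The Th17-like cluster 2, the largest of the CD4 class, held 7 of the 194 cells. Of CD4 class cells, 37.7% were Csf2-positive in cluster 8 (26 of 69, 26.3 to 50.2), 5 of 12 in cluster 17 (41.7%, 15.2 to 72.3) and 30.2% in cluster 10 (22.3 to 39.0), against 20.2% in cluster 7 (15.3 to 25.8), 17.5% in cluster 6 (13.1 to 22.5) and 1.33% in cluster 2 (0.538 to 2.73). By summed counts over all cells of a cluster, Csf2 was highest in the 23 cells of cluster 17, at 9.47 UMIs per 10000 (7.69 to 11.5), then in cluster 10 at 4.71 (4.31 to 5.14), cluster 6 at 2.92 (2.69 to 3.17), cluster 8 at 2.48 (2.28 to 2.69) and cluster 7 at 2.02 (1.80 to 2.26). In a coarser clustering (resolution 0.4) the cluster that overlapped most with both clusters 7 and 10 stood at 3.26 and that of cluster 6 at 0.948. In a finer one (1.2) that of cluster 8 stood at 0.380.

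Of the other effector genes, Ifng and Areg were also highest in cluster 17, while Gata3, Il22, Il10 and Tbx21 were highest in other clusters. Ifng was highest in cluster 17, at 10.2 UMIs per 10000 (8.38 to 12.4), and stood at 3.62 in cluster 6 (3.36 to 3.89), 3.55 in the CD8 cluster 3 (3.33 to 3.77) and 0.637 in cluster 10. Gata3, the master factor of type 2 helper cells, was at 4.80 in cluster 10 (4.40 to 5.24) and at 1.26 in cluster 7 (1.08 to 1.45). Il22 was at 0.835 in cluster 2 (0.748 to 0.929), and Il10 at 1.99 in the Treg-like cluster 15 (1.45 to 2.67) and 1.04 in cluster 5 (0.892 to 1.21). Tbx21 was at 1.51 in cluster 16 (0.970 to 2.25), 1.45 in cluster 3 (1.31 to 1.59) and 1.24 in cluster 17 (0.662 to 2.13). In cluster 7 it was at 1.23 (1.06 to 1.42). Areg, which encodes the tissue-repair factor amphiregulin, stood at 17.2 in cluster 17 (14.8 to 19.9), 13.8 in cluster 15 (12.3 to 15.4), 11.5 in cluster 10 (10.8 to 12.1) and 9.73 in cluster 6 (9.30 to 10.2).

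Within the CD4 class, Ifng, Tbx21, Gata3 and Il13 were found more often in Csf2-positive than in Csf2-negative cells, while Il17a was found in none of the former at this depth. Ifng was found in 32.0% of Csf2-positive cells (25.5 to 39.0) and 20.8% of Csf2-negative cells (18.8 to 22.8). Tbx21 was found in 22.2% (16.5 to 28.7) and 12.2% (10.7 to 13.9), Gata3 in 23.2% (17.5 to 29.8) and 13.8% (12.2 to 15.5), and Il13 in 5.15% (2.50 to 9.28) and 1.26% (0.781 to 1.92). Il17a was found in 0 of 194 Csf2-positive cells (upper bound 1.88%, while 3 cells would make 1.55%), against 2.16% of Csf2-negative cells (1.52 to 2.98). Il22 was also found in 0 of 194 cells, against 1.26% (0.781 to 1.92). As shares of cells, neither difference was detectable at this depth. Over 10 alternatives the Il17a share of Csf2-positive cells was 0 to 1.48%, and it was above 0 at 3000 UMIs and without thinning. The intervals also overlapped for Tnf, at 11.3% and 8.46%, Il10, at 0.515% and 2.88%, and Il7r, at 42.3% and 50.9%. Both groups had similar depths, with medians of 4716.5 and 4770 UMIs. In the CD8 class, at a median of 4910 UMIs, the shares were 0.0836% for Il17a, 0.167% for Il13, 6.23% for Gata3 and 24.5% for Ifng, and in cluster 14 Gata3 was found in 5.80% and Tbx21 in 2.90% of cells. Among Csf2-positive cells the Ifng share was 19.3% at 1000 UMIs and 44.9% without thinning. In clusters 6, 7, 8 and 10, Gata3 was found in 12.8%, 14.6%, 23.1% and 60.5% of Csf2-positive cells. Their Csf2-negative cells stood at 8.56%, 18.9%, 16.3% and 63.6%. Tbx21 stood at 36.2%, 12.5%, 7.69% and 28.9%, against 16.2%, 20.5%, 25.6% and 10.2%. Ifng stood at 44.7%, 33.3%, 34.6% and 7.89%, against 27.0%, 16.3%, 34.9% and 5.68%. So the differences over the whole class were not all seen within clusters.

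**Figure D2:**
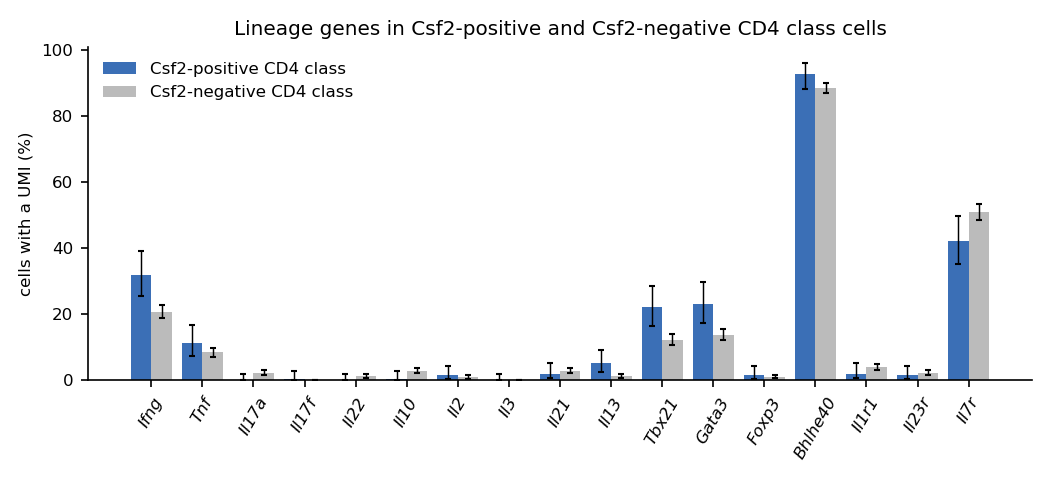
Share of cells with at least 1 UMI of each gene in Csf2-positive (blue) and Csf2-negative (grey) CD4 class cells, in percent, after thinning to 2000 UMIs, with Clopper-Pearson 95% intervals that cover counting error only. Ifng was found in 32.0% and 20.8%, and Il17a in 0 of 194 and 2.16%.

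By summed counts, the chemokines Ccl3, Xcl1, Ccl1 and Ccl4 were higher in Csf2-positive CD4 cells than in Csf2-negative ones, while Ccl5 and Cxcl3 were lower. The first 4 were 9.50-fold (8.49 to 10.6), 7.34-fold (6.43 to 8.39), 6.89-fold (6.34 to 7.49) and 4.30-fold (3.98 to 4.64) higher. Il13 was 6.27-fold higher (4.78 to 8.20), and Il5, from 3 Csf2-positive cells of which 1 held 72.2% of its UMIs, was 17.6-fold higher (9.61 to 33.3). Genes of the Th17 programme were lower. Il17a and Il22 had no UMI in Csf2-positive cells and 347 and 327 UMIs, in 56 and 40 cells, in Csf2-negative ones. A floor of 3 UMIs over the class put them 13.9-fold and 13.1-fold lower. These folds are not lower limits, since each positive cell held several UMIs, and as shares of cells neither difference was detectable. Over the alternatives, the log2 ratio lay between -3.97 and -1.34 for Il17a and between -5.31 and -2.04 for Il22. With 1 cell per clonotype, the log2 ratio of Il13 was 0.84 (-0.13 to 1.74), an interval that holds equality, and that of Ccl4 was 3.24. With at least 2 Csf2 UMIs as the rule for positive cells, Ccl1 and Xcl1 stood at 3.76 and 3.61, and with another thinning seed Gzmk stood at -5.15. Gzmk, a granzyme of memory-like T cells, was at 0.0645 times the level of Csf2-negative cells (0.0294 to 0.123), and the chemokine Ccl5 at 0.244 (0.228 to 0.261).

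Gzmc, another granzyme, was 7.70-fold higher (6.15 to 9.64), Ccdc184 6.40-fold (5.40 to 7.58), Nrp1, a coreceptor, 5.34-fold (3.87 to 7.33), Cd83, an activation marker, 4.98-fold (3.99 to 6.19) and Nrgn 4.51-fold (3.94 to 5.17). Thbs1 stood 8.60-fold higher (4.89 to 15.2), but all 28 of its UMIs in Csf2-positive cells came from 1 cell. Single cells also held 41.8% of the Ccl3 UMIs of Csf2-positive cells, 37.4% of those of Il13, 30.8% of Xcl1, 30.3% of Gzmc, 28.7% of Ccl4 and 25.5% of Ccl1. Il5 and Thbs1 were lower in Csf2-positive cells (log2 ratio -0.48 and -0.53) when the classes were set at 1000 UMIs. Among lower genes, Cd7 stood at 0.155 (0.109 to 0.215), Actn2 at 0.214 (0.151 to 0.295) and Esm1 at 0.0836 (0.0227 to 0.216). Cxcl3, Il10 and Aqp3 had 3, 2 and 2 UMIs in Csf2-positive cells, at ratios of 0.0852 (0.0175 to 0.252), 0.0846 (0.0102 to 0.310) and 0.0932 (0.0112 to 0.342). Phf11c had none and was at least 3.70-fold lower. At 3000 UMIs the log2 ratio was -1.03 for Cxcl3, -1.76 for Cd7 and -1.59 for Actn2, all closer to equality. Cd83 stood at 3.26 with 1 cell per clonotype, and without its top cell Esm1 at -5.55.

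**Figure D3:**
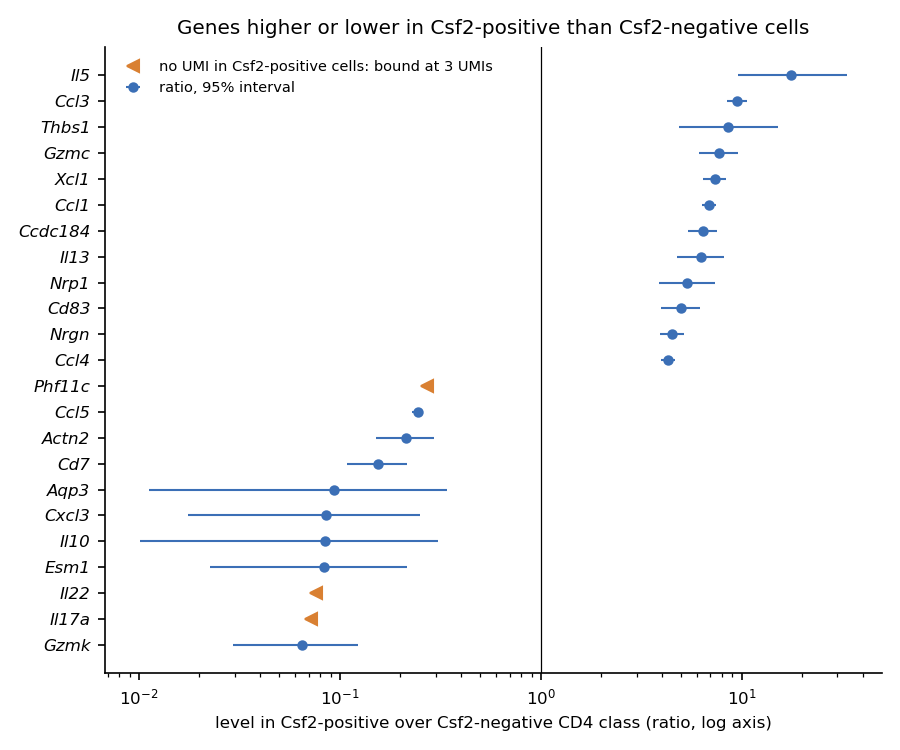
Ratio of the level of each gene shown in Csf2-positive over Csf2-negative CD4 class cells, on a log axis, with 95% intervals that cover counting error only (dots), or at the bound of 3 UMIs for genes without a UMI in Csf2-positive cells (triangles). Ccl3 stood at 9.50 and Ccl5 at 0.244.

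The Th2 list had a median log2 ratio of 1.03 over 7 measured genes, at percentile 100, with Gata3 at 2.35-fold (2.02 to 2.72) and Ccr8, a chemokine receptor of type 2 cells, at 1.93-fold (1.71 to 2.16). The cytokine list stood at 0.78 over 27 genes (percentile 100). The GM-CSF programme list, drawn from other disease models, stood at 0.41 over 16 genes (percentile 100), with Ccl4 above and Il1r1 at 0.278 (0.110 to 0.583). Its median was 0.16 with 1 cell per clonotype and 0.20 without the cell that held most UMIs of each gene. The GM-CSF helper list stood at 0.51 over 5 genes, with Bhlhe40, a factor needed for GM-CSF in other models, at 1.24-fold (1.18 to 1.30). The NF-kappaB target list stood at 0.28 over 12 genes, with Rel at 1.67-fold (1.502 to 1.86), and the checkpoint and activation list at 0.22 over 13, with Tnfrsf9 at 2.45-fold (2.21 to 2.71) and Ctla4 at 0.625 (0.570 to 0.684). The transcription factor list stood at 0.25 over 36 genes, with Nr4a2 at 1.995-fold (1.82 to 2.19) and Eomes at 0.160 (0.0514 to 0.377). The residency list stood at 0.31 over 11 genes and the cytotoxic list at 0.27 over 10, where Klrk1 was 4.48-fold higher (3.66 to 5.46) and Gzmb was at 0.638 (0.574 to 0.708). The dissociation stress list moved with these lists, at a median of 0.62 over 14 genes (percentile 100), with Atf3 at 4.65-fold (3.79 to 5.69) and Egr1 at 2.22-fold (1.88 to 2.60). The log2 ratio of Atf3 was 1.02 with 1 cell per clonotype and that of Egr1 0.39 (-0.17 to 0.93), and with another thinning seed that of Eomes was -5.01.

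The Th17 list had a median log2 ratio of -1.20 over 9 genes and the naive or central memory list of -1.09 over 5, both at percentile 0. In the latter S1pr1, the receptor for exit from tissue, stood at 0.268 (0.155 to 0.433) and Tcf7 at 0.390 (0.263 to 0.559). The gut homing and chemokine receptor list stood at -0.75 over 16 genes (percentile 0), with Ccr9 at 0.270 (0.153 to 0.443) and Cxcr3 at 0.345 (0.254 to 0.458). The interferon response list stood at -0.68 over 6 genes (percentile 0.01), with Irf7 at 0.434 (0.303 to 0.604), and the Tfh list at -0.47 over 6, with Tox2 at 0.487 (0.311 to 0.729) and Pdcd1 at 1.91 (1.72 to 2.11). The Th1 list stood at 0.07 over 8 genes, with Ifng at 1.65-fold (1.47 to 1.85) and Cxcr3 lower. The cytokine receptor, glycolysis, apoptosis, cycling, Treg and CD8 cytotoxic lists stood at -0.08, -0.07, -0.19, -0.14, 0.08 and -0.20, at percentiles 50.2, 54.9, 18.4, 26.2, 91.8 and 14.5. Within the apoptosis list Bcl2, which blocks cell death, was 2.77-fold higher (2.40 to 3.197), and among receptors Il2ra was 1.70-fold higher (1.48 to 1.94). With 1 cell per clonotype, the intervals of Il2ra (log2 ratio 0.16, -0.22 to 0.53) and Tox2 (-1.23, -2.91 to 0.09) held equality, and Bcl2 stood at 0.76. At 1000 UMIs Tcf7 stood at -2.04. The macrophage list stood at 0.27 over 3 genes, and of its Lyz2 UMIs in Csf2-positive cells 81.4% lay in 1 cell. The NK or ILC list stood at 0.84 over 6 genes, with Fcer1g at 2.72-fold (1.86 to 3.90) and 51.2% of its UMIs in 1 cell. When all cells without Cd8 UMIs formed the class, the log2 ratio was -0.91 for Lyz2 and -0.41 for Fcer1g, the latter with an interval that held equality (-0.86 to 0.01).

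In Foxp3-positive CD4 cells, 20 cells against 1841, genes of the Treg list were higher, as were single genes such as Klrg1 and Gzmb. Klrg1 was 13.5-fold (8.52 to 20.5), Il10 11.8-fold (7.05 to 18.8), Ikzf2, a Treg transcription factor, 8.81-fold (6.15 to 12.3) and Gzmb 8.64-fold higher (7.79 to 9.55). Izumo1r was 8.20-fold (5.96 to 11.0), Itgae 9.99-fold (5.46 to 16.99) and the chemokine receptor Ccr2 6.03-fold higher (4.81 to 7.48). By summed counts, Csf2 stood at 0.320 of the level of Foxp3-negative cells, from 5 UMIs (0.104 to 0.748), and Ifng at 0.525 (0.262 to 0.942). As shares of cells, a lower Csf2 was not seen. Foxp3 was found in 3 of 194 Csf2-positive cells (1.55%, 0.320 to 4.45) and 17 of 1667 Csf2-negative ones (1.02%, 0.595 to 1.63). With another thinning seed, the interval of Ifng held equality (log2 ratio -0.87, -1.94 to 0.01). The macrophage-list gene Cd68 was also higher, at 11.1-fold (3.90 to 25.6) from 6 UMIs in 4 cells, while Lyz2 had no UMI. The Treg list had a median log2 ratio of 1.66 over 7 genes (percentile 100) and the cycling list of -1.57 over 9 (percentile 0). The Th2, checkpoint and activation, and gut homing lists stood at 1.45, 0.80 and 0.74, with Areg at 3.59-fold (3.02 to 4.24), Tnfrsf9 at 5.81-fold (4.78 to 7.02) and Ccr9 at 5.46-fold (3.50 to 8.16), 56.0% of the latter in 1 cell. Rnase4, Rasgrp4, Neb, Pvrig and Chchd10 were 16.8-fold (8.01 to 31.9), 13.2-fold (6.08 to 25.5), 9.66-fold (5.70 to 15.5), 9.84-fold (5.11 to 17.4) and 7.66-fold (4.79 to 11.7) higher. Among lower genes, the chromatin gene Hmgb2 stood at 0.419 (0.329 to 0.526), Serpinb9 at 0.193 (0.0628 to 0.452), Ckb at 0.221 (0.0718 to 0.518) and Hist1h1e at 0.206 (0.0560 to 0.527). Pclaf and Tgfbr2 had 3 and 2 UMIs, at 0.124 (0.0255 to 0.363) and 0.141 (0.0171 to 0.510). Hist1h1b, Hist1h2ae, Cd160, Dnmt1, Chd9 and Tff1 had no UMI and were at least 6.07-fold, 4.83-fold, 3.196-fold, 2.47-fold, 2.41-fold and 2.40-fold lower. Of the Il10 UMIs 55.0% lay in 1 cell, and 54.5% of those of Rnase4. Without the top cell of each gene, the log2 ratios were 2.56 for Il10, 2.995 for Rnase4 and -1.99 for Hmgb2. At 1000 UMIs they were -3.60 for Csf2, -4.12 for Ckb and -2.02 for Ifng, and without thinning 4.72 for Klrg1.

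Most T cells with a receptor belonged to expanded clones. A clonotype was assigned to 2628 kept cells (49.3%), which held 826 clonotypes, and 224 of these had 2 or more cells. The largest clonotype, a CD8 clone, had 263 cells, and the 10 largest held 30.6% of cells with a clonotype. Of cells with a clonotype, expanded clonotypes held 75.9% of 885 CD4 class cells (73.0 to 78.7) and 80.9% of 1270 CD8 class cells (78.7 to 83.1). The share was lower in Csf2-positive CD4 cells, at 56.6% of 76 cells (44.7 to 67.9), than in Csf2-negative ones, at 77.8% of 809 (74.7 to 80.6). However, only 39.2% of the Csf2-positive and 48.5% of the Csf2-negative cells had a clonotype, so unequal recovery may enter this difference. It was 27.4% of cells with a clonotype in cluster 7 (18.7 to 37.5) and 23.6% in cluster 10 (13.2 to 37.0), against 86.4% in cluster 6 (80.6 to 91.0) and 82.6% in cluster 2 (78.4 to 86.3). Only 25.7% and 26.8% of the cells of clusters 7 and 10 had a clonotype. By the TRB CDR3 of any contig, marked productive or not, the expanded share was 34.2% of 301 cells in cluster 7 and 21.2% of 151 in cluster 10, an alternative chosen after seeing the data.

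**Figure D4:**
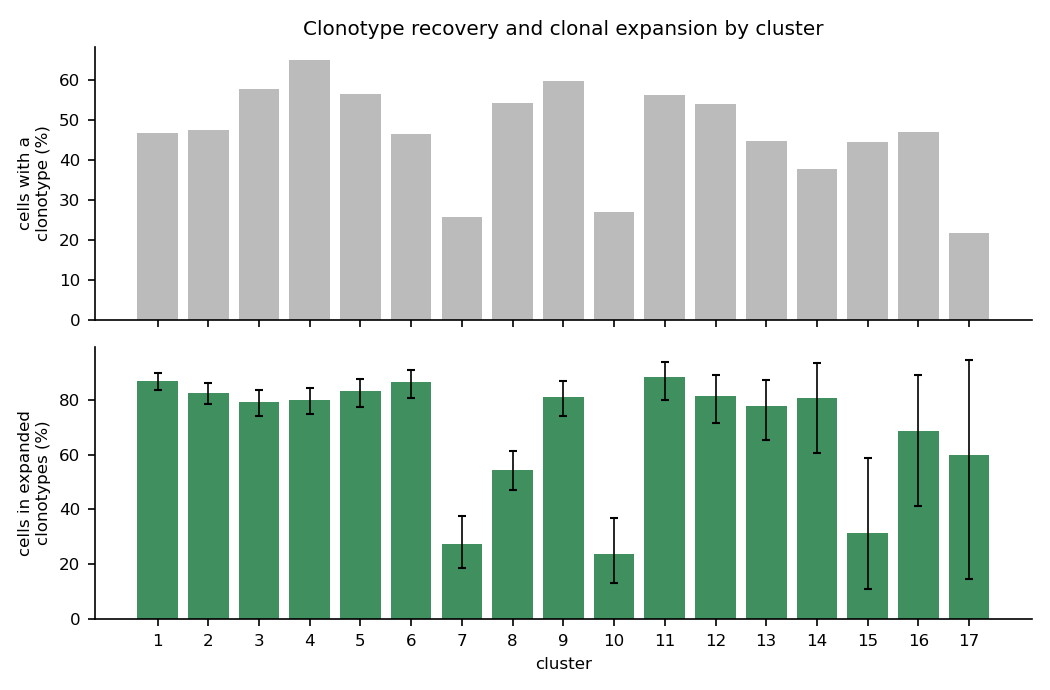
Share of cells with an assigned clonotype (top) and share of those cells in clonotypes of 2 or more cells (bottom, with Clopper-Pearson 95% intervals that cover counting error only), in percent, by cluster. Clusters 7 and 10 stood at 27.4% and 23.6% in the lower panel.

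Cells of a clonotype were nearly always of 1 class: 99.7% of same-clonotype pairs agreed in class, against 52.5% for independent pairs, and 9 of 1677 classed cells were in the minority class of their clonotype. Csf2 was found in 9.71% of the CD4 clone-mates of Csf2-positive cells, against 5.99% of CD4 cells of expanded clonotypes. With clonotypes weighted equally it was 13.2%, and at 3000 UMIs per cell, where Csf2 is found more often, 15.2%. The 39 positive cells behind it give an interval of 2.58% to 23.5%, which holds the share of expanded clonotypes, so a difference was not detectable. The same pair of values was 27.4% and 22.9% for Ifng, 30.6% and 24.7% for Gzmb, 4.95% and 2.15% for Il17a, and 3.61% and 1.84% for Il22. With clonotypes weighted equally, the clone-mate shares of these genes were 14.3%, 21.0%, 4.31% and 2.57% in the same order. The shares of expanded clonotypes weight cells, so for equal weights they are not a like base. Foxp3 was found in none of the clone-mates of its 7 positive cells.

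Of the 5 pairs of CD4 clusters compared, clusters 5 and 6 had the highest ratio of same-clonotype pairs, while clusters 2 and 9 shared the most clonotypes. Clusters 5 and 6 shared 21 clonotypes and held 2.43 times the same-clonotype pairs that independence gives. The Th17-like cluster 2 and the cycling cluster 9 shared 30 clonotypes, at 1.09 times. Clusters 2 and 6 stood at 0.253 times and clusters 6 and 7 at 0.208 times. Clusters 7 and 10 shared 2 clonotypes, at 0.0228 times independence, but pairs within cluster 7 and within cluster 10 also stood low, at 0.0401 and 0.321 times. In the CD4 class alone, an alternative chosen after seeing the data, these ratios were 3.11, 1.44, 0.312, 0.377 and 0.0581 in the same order. Without the largest clonotype, a CD8 clone, the first 4 were 4.85, 2.20, 0.508 and 0.416, and with the coarser clustering clusters 5 and 6 stood at 1.29 and clusters 6 and 7 at 0.0581.

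Among V beta segments, clonotypes with a Csf2-positive cell used TRBV3 most often, in 11 of 62 (17.7%, 9.20 to 29.5). Of 289 clonotypes with a Csf2-negative cell, 37 used it (12.8%, 9.18 to 17.2), which overlap within counting error. Among V alpha segments TRAV4D-4 was the most frequent, in 14 of 62 (22.6%, 12.9 to 35.0) and 44 of 289 (15.2%, 11.3 to 19.9), with overlapping intervals too. In cells whose RNA was led by Trbv26, 81.0% of TRB contigs were called TRBV3 and 2.79% of cells had a productive TRB contig. By contig calls, of 3937 cells with a productive TRA chain, 0 had the invariant chain of natural killer T cells (upper bound 0.0937%, while 3 cells would make 0.0762%). That of mucosal-associated invariant T cells was found in 3 (0.0762%, 0.0157 to 0.223). Such calls can miss a segment, since no contig was called TRBV26, so both shares hold for calls and may not hold for cells.

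Markers of other cell types were found in few of the cells outside cluster 14. At least 2 macrophage genes were found in 2.57% of kept cells (2.16 to 3.03), and in 87.0% of cluster 14 (76.7 to 93.9). At least 2 genes of the NK or ILC list were found in 4.73% (4.17 to 5.33), including 41 of the 205 cells of cluster 10. The members of this list that were 2-fold higher in cluster 10 were Il1rl1, also on the Th2 list, and Hs3st1, its leading gene. The list thus does not set these cells apart from Th2-like T cells. The gamma delta T list was met by 38 cells (0.713%, 0.505 to 0.977), including 3 of the 23 cells of cluster 17 (13.0%, 2.78 to 33.6). Plasma cell, epithelial, endothelial, neutrophil, dendritic and fibroblast lists were met by 9, 11, 11, 5, 4 and 2 cells, and B cell, mast cell and erythroid lists by none of 5333 cells at this depth.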

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

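The tests below of clusters 7 and 10, of Trbv26 and of cluster 14 were chosen after the results were seen, except those of cells without a receptor and of superantigens. Signals in data that no comparison used are given first. The TCR table held 847 barcodes that are not in the RNA matrix. In 598 kept cells a TRB CDR3 was found only in contigs not marked productive. A Trbv26 UMI was found in 25.3% of Csf2-positive CD4 class cells (19.3 to 32.0), against 10.4% of Csf2-negative ones (8.95 to 11.9) and 1.76% of the CD8 class, although no contig was called TRBV26.

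Few cells of clusters 7 and 10 had a productive TRB contig, 36.5% (32.6 to 40.6) against 66.0% in the other CD4-majority clusters. Lower depth of these cells is argued against, since among cells of 2000 to 5000 UMIs the share was still 31.1% (26.7 to 35.8) against 60.3%. Whether cells without a T cell receptor were part of the cause stays open. A TRB contig or a Trbc UMI was found in 93.2% (90.8 to 95.1), against 96.6% in the other CD4-majority clusters. The deeper cells of cluster 14 stood at 66.7% (54.3 to 77.6), but they held T cell transcripts too and give no receptor-free background. Contigs not marked productive also counted, so the share cannot decide it. In cluster 10, 85.4% of cells had any contig, against 93.0% in cluster 7, and 41 of 205 met the NK or ILC list. The members of that list raised in cluster 10 were Il1rl1, also a Th2 list gene, and Hs3st1, so the list does not tell receptor-free cells from Th2-like ones. Cells whose V beta UMIs were at least 80% Trbv26 or Trbv13-2 made up 54.5% of cells led by a segment in clusters 7 and 10 and 20.9% elsewhere, and only 1.95% and 7.61% of them had a productive TRB contig, while cells led by other segments reached 78.4% (71.4 to 84.3) and 83.7%. A candidate explanation is thus the annotation of these segments, since 81.0% of TRB contigs in Trbv26-led cells were called TRBV3. No further explanation was tested.

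Trbv26, the V beta 3 segment (chromosome 6, 41227505 to 41227993, mm10), was frequent in clusters 7 and 10, at 45.4% of cells (41.3 to 49.6) against 3.69% of the other CD4-majority clusters (2.92 to 4.59), which argues against free RNA, and a single clone is argued against, since the most frequent CDR3 took 14.8% of 229 Trbv26-led cells. A response to superantigens of Balb/c mice, which select T cells by V beta, would also reach Trbv12-1, Trbv12-2, Trbv15 and Trbv16, whose cells were Csf2-positive in 23.9% of 88 (15.4 to 34.1) against 8.23% of 996 with the remaining segments, which met the bound set before these shares, though not that of Trbv26, were seen. The shares of the 4 segments, with overlapping intervals, were 42.1% for Trbv12-1 (20.3 to 66.5), 23.1% for Trbv16 (8.97 to 43.6), 17.9% for Trbv15 (6.06 to 36.9) and 13.3% for Trbv12-2 (1.66 to 40.5), and Trbv13-1 and Trbv23, outside the set, stood at 21.2% and 38.9%. It is a candidate explanation that stays open, since 3 ways to weight clones, all added after the first value was seen, differed: CDR3s with any positive cell, a measure that rises with clone size, made up 27.4% (17.6 to 39.1) and 19.9% (14.9 to 25.7), which missed the bound, while 1 cell per CDR3, which replaced it in the test, gave 27.4% and 14.6% (10.3 to 19.9), with overlapping intervals, and the mean share per CDR3 was 24.7% and 13.1%. Within cluster 7 the Csf2-positive share was 23.0% in Trbv26-led and 18.9% in other led cells, and within cluster 10 it was 38.7% and 30.4%, with overlapping intervals. Of classed cells led by the 4 segments, 20.1% were of the CD4 class, against 92.7% for Trbv26 and 47.3% for the remaining segments. Clusters 7 and 10 held 31.8% of the CD4 class cells led by the 4 segments, against 77.6% and 9.24% in the same order. Of all cells so led they held 9.50%, against 76.9% and 5.29%.

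Cluster 14 held macrophage transcripts in a sort for T cells, such as Lyz2 at 32.1 and C1qb at 6.06 UMIs per 10000. Free RNA is argued against, since the macrophage list stood 47.2 times above the highest other cluster. Macrophages without a T cell are argued against as the source of the whole cluster, since Cd3e, Trac and Trbc stood at 44.6% of their level in all kept cells (34.1 to 57.1 over resampled cells), above the 9.48% of Cd8 genes in CD4-majority clusters and the 14.9% of Cd4 in CD8-majority ones, which bound free RNA, but they stay open for part of it. Doublets of a macrophage and a T cell are a candidate explanation. The median Cd3e plus Trac level of the cluster's cells with at least 2 macrophage genes was 41.0% of that in other clusters. Their median was 7426.5 UMIs against 4800. However, the 9 cells of the cluster with fewer than 2 macrophage genes were as deep, at 7360. Fibroblast, epithelial and neutrophil markers were raised in the cluster too. No biological explanation was tested.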

How the results depend on the processing

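Of 202 values of the main results under the alternatives 175 stayed within their interval, and of 2187 values of named genes 1956 did, 219 moved and 12 reversed, over 7 of 193 genes, where a reversal was counted only if the reported interval excluded equality; 5 further values of 4 genes, all with intervals holding equality (Egfl7 in CD4 over CD8, and Krt18, Lyz2 and Xbp1 in Foxp3-positive cells), changed sign, and the other 217 that moved kept it. Of the alternatives, those with the any-contig CDR3, the CD4 class alone for sharing, and without the top cell per gene, the deepest 5% of cells, clusters 10 or 14 or the largest CD4 clonotype were chosen after seeing the data. The Csf2 share of the CD4 class follows depth, at 7.25% with 1000 UMIs, 12.03% with 3000 and 14.7% without thinning, as does the Ifng share of Csf2-positive cells, at 19.3% with 1000 and 44.9% without. In the clusters that overlapped most, the Csf2 level was 3.26 for both 7 and 10 and 0.948 for 6 at resolution 0.4, and 0.380 for 8 at 1.2. With 1 cell per clonotype the GM-CSF programme median was 0.16, that of the cytotoxic list in CD4 over CD8 cells -1.02, and Pclaf (Csf2, 0.11) and Xbp1 (CD4 over CD8, -0.049) reversed; without the top cell the programme median was 0.20, and without the largest clonotype the cytotoxic median was -1.70. Expanded shares of the CD4 and CD8 class were 80.9% and 87.0% by TRB alone and 70.3% and 78.0% by the deposited identifiers, and that of CD8 was 76.1% without the largest clonotype and 86.1% by the any-contig CDR3. Sharing of clusters 6 and 7 and of 5 and 6 was 0.0581 and 1.29 at resolution 0.4, and 0.416 and 4.85 without the largest clonotype, where 2 and 9 stood at 2.20 and 2 and 6 at 0.508; 2 and 6 stood at 0.488 at 1.2 and 0.478 by the any-contig CDR3. In the Csf2 comparison, log2 ratios reversed for Il5 (-0.48), Lyz2 (-0.88) and Thbs1 (-0.53) with 1000 UMIs, Thbs1 (-2.86) with 3000, Fcer1g (-0.41), Lyz2 (-0.91) and Thbs1 (-0.68) with all cells lacking Cd8, and Lyz2 (-1.13 without the deepest cells, -0.63 without its top cell); Foxp3-positive Nfkbia was -0.0058 with seed 1. Apart from merged clusters and changed depth, the cause was not tested. Ratios of clusters that merged have no value. For the numbers of cells and clusters, the interval used to count values that stayed was a set range around the value. For list medians it ran between the medians of the members' bounds. Omitting doublet removal moved nothing, since no doublet was called, and genes with few UMIs in 20 Foxp3-positive cells are limited by depth.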

Other observations

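The values of this part were chosen after the data were seen, apart from the levels of Csf2, Ifng and Il17a. Cluster 17, of 23 cells, 12 of the CD4 and 7 of the CD8 class, had high levels of several effector genes. It reached 4 markers of the Th17 list, among them Tmem176a and Tmem176b, and 3 of the GM-CSF helper list, Csf2, Tnf and Il1r1. Csf2 stood at 9.47 UMIs per 10000 in it and 0.805 in all other cells, Ifng at 10.2 and 2.06, Tnf at 3.16 and 0.401, and Areg at 17.2 and 2.75. The interleukin 1 receptor gene Il1r1 stood at 2.29 and 0.102, while Il17a was at 0.765 and 0.144, from 8 UMIs in 2 of the 23 cells, and Ccr6 and Il22 had no UMI in the cluster. The neuropeptide receptor component Ramp1 was at 8.89 and 0.192 and the chemokine receptor Cxcr6 at 11.4 and 3.50.

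The cells of cluster 17 also shared receptor segments. A Trav12-2 UMI was found in 15 of 23 cells (65.2%, 42.7 to 83.6), against 2.86% of other cells (2.43 to 3.35), and Trbv13-2 led 12 of the 19 cells with a leading segment (63.2%, 38.4 to 83.7), against 13.7% of other such cells (12.6 to 14.9). Among 10 cells with a TRB CDR3 there were 8 distinct ones, and the most frequent was found in 3 cells, all in cluster 17.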
